A study of Mus musculus with 18 samples.

How the data were processed

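The series holds 18 Affymetrix Mouse Gene 1.0 ST arrays of intra-abdominal white adipose tissue, biceps femoris muscle and liver from cachectic and control mice, with 3 arrays in each of the 6 groups. The deposited values are log2 intensities that the authors made with robust multi-array averaging (RMA), per the submitters' processing notes, and they were used as deposited. The value table holds 35556 probesets, 0 missing values and a range of 2.72 to 14.49, and the array medians lie between 6.91 and 7.15. The labels do not say which arrays of different tissues share an animal, nor do they state that the 3 arrays of a group are separate animals, so the p-values measure the spread between these samples. No scan date or hybridization batch is given in the sources used here.

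Probesets were named from the platform annotation, in which 21789 probesets carry 1 gene, 1621 several genes and 12146 none. Gene names were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, used for names and for no coordinates. Of the single-gene probesets 21698 were found there, and 0 symbols were updated. Analysis by gene used the 19938 genes with a single-gene probeset. For the 999 genes with more than 1, the probeset with the highest mean was taken. Kras has no probeset of its own and was not analysed here.

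Within each tissue, genes were kept when they passed the 40th percentile of intensity in the tissue, which left 11918 genes in adipose tissue, 11891 in muscle and 11920 in liver. A linear model with a moderated t-test and an intensity trend in the variance prior was fitted per tissue with limma 3.58.1 in R 4.3.3. The p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was required. Differences between tissues were tested as interaction contrasts in 1 model of all 18 arrays, on genes kept in both tissues. The overlap of called genes between tissues was tested with Fisher's exact test. The smallest two-sided p that an exact test can give for 3 arrays against 3 is 0.1, so a model that shares information across genes was used.

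The design of the comparisons, the alternatives, the rule for naming genes and 47 lists (26 of genes and 21 of cell markers) were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with the rotation test fry. Per tissue, the text names the 8 called genes with the largest rise and the 8 with the largest fall whose 3 cachectic values all lie beyond the 3 control values, filled to 5 by smallest p where fewer passed. It draws on up to 4 called members with the largest change per list, or 2 with the smallest p where none was called, and on the 5 largest differences per pair of tissues. The genes of the engineered alleles and Xist are also named. Predicted genes without an official symbol are counted and not named among the largest changes. Genes named outside this rule are said to have been chosen after their values were seen. After the data were examined, 2 lists were added, the first of milk proteins and secretory mammary epithelium (10 genes) and the other of mammary basal and luminal keratins (6 genes). Their median changes were 1.32 and 0.02 in adipose tissue and 1.64 and 0.91 in muscle, and they were used for describing arrays and not for list tests.

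The procedure was tested on simulated data, in which 200 genes per tissue were shifted by known amounts. A log2 change of 1 was recovered for 16% of genes in adipose tissue, 28% in muscle and 74% in liver, and a change of 2 for 64%, 80% and 96%. A difference of 2 between adipose tissue and liver was recovered for 77.5% of genes. Of the calls made, 3.45% in adipose tissue, 0.98% in muscle and 8.05% in liver were genes that had not been shifted. The simulated genes were drawn independently of each other, without the differences in sex and tissue content that the real arrays share across genes. These rates therefore need not hold for the real data. With 3 arrays per group the number of arrays limits the precision, and changes under 1 log2 unit in adipose tissue and muscle are mostly missed at this size.

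Alternatives to the filter, the normalization, the variance prior, the array weights, the probeset choice, the covariates and the arrays included were run 1 at a time, and each array was left out in turn. Array weights stopped before convergence in some fits. The other splits of the 6 arrays of a tissue into 3 and 3 (10 with the real one) and 100 drawn splits for the comparisons between tissues were fitted in the same way. For the comparisons between tissues a fit was added in which arrays in the same place of the sample order form 1 block, since those of muscle and liver deviate together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Probesets with several genes or none were left out of the analysis by gene and counted apart.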

Results

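Expression was profiled in intra-abdominal white adipose tissue, biceps femoris muscle and liver of cachectic and control mice aged 10 weeks, on 18 arrays with 3 arrays in each of the 6 groups. The cachectic mice develop pancreatic adenocarcinoma because Cre recombinase, driven by the promoter of the pancreatic transcription factor Pdx1, switches on a mutant Kras allele and deletes the Cdkn2a locus. The control mice carry both engineered alleles without Cre. The study set out to describe which pathways respond in each of the 3 wasting or metabolic tissues. The 18 array medians lay between 6.91 and 7.15 log2 units. Kras was not analysed here, because no probeset carried its name alone. In the tissues profiled, outside the organ where the alleles are recombined, Cdkn2a lay at 7.01 ± 0.03 (SD, n = 3) in cachectic and 7.08 ± 0.04 in control adipose tissue. It lay at 7.07 ± 0.10 and 7.10 ± 0.09 in muscle, and at 7.13 ± 0.17 and 7.46 ± 0.19 in liver. Pdx1 lay at group means of 6.12 to 6.38, below the intensity required for testing in every tissue.

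The arrays of each group were mixed in sex and in tissue content. Xist, the transcript of the inactive X chromosome, lay between 11.83 and 12.91 on 2 of 3 arrays of every group and between 5.57 and 6.25 on the remaining array. The Y-linked gene Eif2s3y, chosen after its values were seen, was high on that array. Milk protein level followed Xist, since 10 of the 12 arrays with high Xist lay above 6.30, the highest level of an array with low Xist. Transcripts of milk proteins and secretory mammary epithelium averaged 13.55 on cachectic adipose array 2, 11.31 on cachectic adipose array 3 and 11.12 on control adipose array 2, against 6.07 on cachectic adipose array 1. In muscle they averaged 13.35 on cachectic array 2, 10.37 on control array 3 and 8.60 on cachectic array 3, against 5.85 on control array 2. In liver they averaged 9.0 and 8.11 on cachectic arrays 2 and 3, and no more than 5.92 on the other 4 arrays. Hepatocyte markers averaged 11.44 on cachectic adipose array 3 and 9.73 on cachectic muscle array 1, and mesothelial markers 9.43 on cachectic liver array 3.

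**Figure D1:**
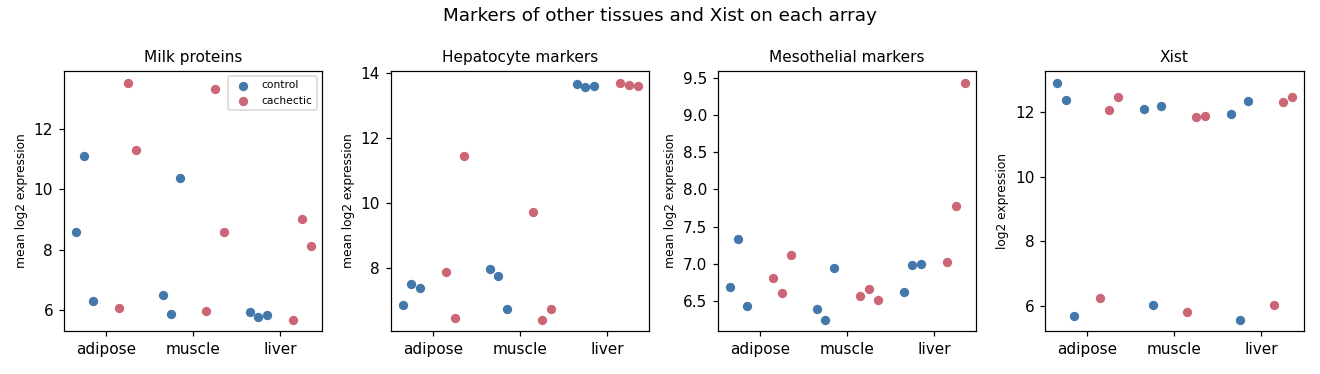
Mean log2 expression of the milk protein list, the hepatocyte markers and the mesothelial markers, and log2 expression of Xist, on each of the 18 arrays by tissue, with control arrays in blue and cachectic arrays in red. Milk protein levels reach 13.55 in adipose tissue and 13.35 in muscle, and Xist is high on 2 of 3 arrays of every group.

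In adipose tissue the transcript of neuronatin (Nnat, probeset 10477986), a small membrane proteolipid, fell by 5.77 on the log2 scale (SE 0.38), from 12.55 ± 0.75 (SD, n = 3) in control to 6.78 ± 0.20 (SD, n = 3) in cachectic mice. The cachectic mean lay under the intensity filter of 6.99, and a difference from such a mean is not exact. It was the 1 gene of 11918 tested that passed (limma, adjusted p = 0.0222), and its 3 cachectic values all lay below the 3 control values. The next genes by p did not pass. Leptin (Lep), the adipocyte hormone that signals fat stores, had a log2 change of -5.17 ± 0.58 (SE) with an adjusted p of 0.0687. The collagen chains Col6a3 and Col15a1 had changes of -2.55 ± 0.24 and -2.18 ± 0.23. Aldh1a7, an aldehyde dehydrogenase, stood at -2.74 and Glb1l2 at -4.12, each with an adjusted p of 0.0687. On the higher side the immunoglobulin genes Ighg3 and Igha had changes of 3.64 ± 0.40 and 2.73 ± 0.38, the acute-phase gene Saa3 one of 2.89 ± 0.36. The glucocorticoid-induced genes Fkbp5 and Cebpd had changes of 2.01 ± 0.25 and 1.77 ± 0.25 (adjusted p from 0.0687 to 0.0839 over these 5 genes). The lower mean also lay under the filter for Lep (6.35), Aldh1a7 (6.50), Glb1l2 (6.42), Ighg3 (5.87) and Saa3 (6.22).

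The single adipose call stood beside 965 genes at an unadjusted p under 0.05 and 1628 genes (13.7%) whose 2 groups of 3 arrays did not overlap, where chance gives 10%. For Nnat in adipose the adjusted p was 0.0830 without cachectic array 1, 0.195 without control array 1, 0.0668 without control array 3 and 0.111 without cachectic array 3, so that 0 genes were called in each of these fits. Without cachectic array 2, 10 genes were called. The call remained without cachectic array 2 and control array 2, the array of each group with the most milk protein transcripts (1 gene), a fit that kept cachectic array 3 with a milk protein level of 11.31. The fit of all 18 arrays, which shares 1 estimate of the spread, called 254 genes. With the hepatocyte level as a covariate 0 genes were called, and for Nnat in adipose the limma adjusted p was 0.104.

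Fat cell, lipid synthesis and matrix genes were lower in cachectic adipose tissue as groups. Of 14 adipocyte identity genes, 14 had a negative change, with a median of -1.04 log2 units, and 7 passed adjusted over the list alone, against 0 over all genes (camera, adjusted p = 1.15e-08; adjusted p = 0.401 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis, 17 had a negative change, with a median of -1.25, and 7 passed adjusted over the list alone, against 0 over all genes (adjusted p = 4.63e-06; adjusted p = 0.401 with an estimated correlation). Dgat2, which makes triglycerides, stood at -2.00 ± 0.24 (SE) and Pnpla3 at -3.20 ± 0.59. The 25 matrix and fibrosis genes had a median of -0.83 with quartiles of -2.19 and 0.19, and 13 passed adjusted over the list alone, against 0 over all genes (adjusted p = 2.22e-07; adjusted p = 0.401 with an estimated correlation). The collagen genes Col6a3 (-2.55) and Col1a1 (-2.59 ± 0.33) led it. Of 12 fibroblast markers 10 were negative, with a median of -1.15, 0 called over all genes and 6 adjusted over the list alone (adjusted p = 1.06e-05; adjusted p = 0.401 with an estimated correlation). All 40 genes of oxidative phosphorylation tested had a negative change, with a median of -0.44, and 0 passed either way of adjusting (adjusted p = 1.38e-11; adjusted p = 0.401 with an estimated correlation).

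Glucocorticoid-induced genes were higher in cachectic adipose tissue, with 16 of 18 positive, a median of 0.92, 0 called over all genes and 6 adjusted over the list alone (camera, adjusted p = 2.48e-10; adjusted p = 0.401 with an estimated correlation). Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, had 14 of 16 positive, a median of 0.76, 0 called over all genes and 6 adjusted over the list alone (adjusted p = 1.52e-10; adjusted p = 0.401 with an estimated correlation). Macrophage markers had a median of 0.55 with 15 of 16 positive, 0 called over all genes and 1 adjusted over the list alone (adjusted p = 2.35e-05; adjusted p = 0.488 with an estimated correlation). Their median was 0.28 without control array 1 and 0.31 without cachectic array 3. Itgam stood at 1.64 ± 0.34 (SE). Neutrophil markers had a median of 1.15, 0 called over all genes and 1 adjusted over the list alone (adjusted p = 0.00138; adjusted p = 0.401 with an estimated correlation). Acute-phase genes had a median of 1.08, 0 called over all genes and 2 adjusted over the list alone (adjusted p = 3.60e-05; adjusted p = 0.426 with an estimated correlation). Without cachectic array 3 their median was 0.50 (limma camera, adjusted p = 0.0887). That array carried hepatocyte transcripts, and the hepatocyte markers themselves, with a median of 1.57 (adjusted p = 0.00200; adjusted p = 0.509 with an estimated correlation), stood at -0.18 without it (adjusted p = 0.880) and at 2.55 without cachectic array 2. The 12 B and plasma cell markers were not called (limma camera, adjusted p = 0.965), with Jchain at 2.42 and Ighm at 2.21 among 5 positive and 7 negative members.

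Counted together, 21 of the 35 lists tested in adipose tissue passed camera with its preset correlation, 12 higher and 9 lower. None passed with an estimated correlation, with adjusted p from 0.401 to 0.655 over these 21 lists, and 0 passed the rotation test fry. Regroupings of the same 6 arrays that mixed cachectic with control mice gave up to 19 lists. The narrower adipocyte marker list had a median of -0.87 (adjusted p = 0.401 with an estimated correlation), and -0.55 without cachectic array 2. Fatty acid oxidation had a median of -0.42 (adjusted p = 0.509 with an estimated correlation). It was not called without control array 1 (-0.53; limma camera, adjusted p = 0.0517), without control array 3 (-0.25, 0.213), without a filter (-0.35, 0.0609) or with the milk protein covariate (-0.29, 0.0681). Its median was -0.74 without control array 2 and -0.64 without cachectic array 3. Cholesterol synthesis had a median of -0.41 (adjusted p = 0.498 with an estimated correlation) and was not called without control array 2 (-0.27; limma camera, adjusted p = 0.159). Its median was -0.25 without cachectic array 1 and -0.68 without control array 1. Cell cycle genes had a median of -0.88 (adjusted p = 0.655 with an estimated correlation) and of -0.11 without control array 2 (limma camera, adjusted p = 0.620). It was -0.013 without control array 2 and cachectic array 2, the array of each group with the most milk protein transcripts (limma camera, adjusted p = 0.462).

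The remaining higher lists in adipose tissue had medians that moved with single arrays, and each had an adjusted p = 0.401 with an estimated correlation. The unfolded protein and integrated stress response had a median of 0.38, and of 0.20 and 0.19 without control array 1 and cachectic array 3. Hepatic cytochrome P450 genes had a median of 0.68 and were not called without cachectic array 3 (0.47; limma camera, adjusted p = 0.109) or control array 1 (0.52, 0.0860). JAK-STAT genes had a median of 0.16, and of 0.27, 0.34, 0.03, 0.31 and 0.25 without cachectic arrays 1, 2 and 3 and control arrays 2 and 3. Atrophy genes had a median of 0.13, and of 0.08 without cachectic array 3. Circadian clock genes had a median of 0.17 and were not called without cachectic array 1 (0.16; limma camera, adjusted p = 0.0944) or control array 2 (0.08, 0.139). Their median was 0.37, 0.28 and 0.43 without cachectic arrays 2 and 3 and control array 3. Autophagy and lysosome genes had a median of 0.08 and were not called without cachectic array 2 (-0.03; limma camera, adjusted p = 0.0766), cachectic array 3 (0.08, 0.0538) or control array 2 (0.03, 0.103). Their median was 0.15 and 0.05 without cachectic array 1 and control array 1. Without cachectic array 2 and control array 2 together, circadian clock genes (0.12; limma camera, adjusted p = 0.0905) and autophagy and lysosome genes (0.03, 0.205) were not called.

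In muscle 62 genes rose and 208 fell of 11891 tested (limma), 37 and 176 of them by at least 1 log2 unit. Mettl21e (probeset 10354299), which encodes a protein methyltransferase of skeletal muscle, fell by 4.56 on the log2 scale (SE 0.17), from 9.41 ± 0.26 (SD, n = 3) to 4.85 ± 0.09 (SD, n = 3; limma adjusted p = 0.00101). Nnat fell by 4.55, from 11.08 ± 0.51 to 6.53 ± 0.28 (limma adjusted p = 0.00733). Cardiac alpha-actin (Actc1) fell by 3.82, from 13.46 ± 0.30 to 9.64 ± 0.63 (limma adjusted p = 0.0105). Other large falls were those of the phospholipase Plcd4 (-3.91), the integrin subunit Itgb6 (-3.86), the muscle protein Ky (-3.61), Nrep (-3.49) and the collagen-binding proteoglycan fibromodulin (Fmod, -3.48), with adjusted p from 0.00871 to 0.0245. The cachectic means of Mettl21e, Nnat, Itgb6 (5.92) and Ky (6.93) lay under the intensity filter of 6.96, so the sizes and the order of these falls are not exact. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 4.27-fold, from 9.10 ± 0.19 to 11.20 ± 0.09 (limma adjusted p = 0.00871). The interleukin 6 receptor gene Il6ra rose 3.93-fold, from 9.21 ± 0.12 to 11.19 ± 0.31 (limma adjusted p = 0.0146). Lysozyme (Lyz1, log2 change 2.75), the calcium sensor Doc2b (2.72), the B cell chemokine Cxcl13 (2.71), the acute-phase gene Itih4 (2.29), the zinc importer Slc39a14 (2.15) and the mitochondrial acetyl-CoA synthetase Acss1 (1.93) also rose, with adjusted p from 0.0271 to 0.0475. The rule for naming required that the 3 cachectic values of these 16 genes lie beyond the 3 control values on 1 side, so that separation is not a further result.

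The groups of 3 arrays did not overlap for 3482 genes (29.3%) in muscle, where chance gives 10%. The count of 270 genes was 4, 3 and 6 without control array 1, 2 or 3, 41 without cachectic array 3 and 1895 without cachectic array 2, the array richest in milk protein transcripts. Without that array and control array 3, the control array richest in them, 838 genes were called, 513 higher and 325 lower, among them 236 of the 270. Of 35 named genes called in muscle, Mettl21e alone passed with each array left out in turn. None changed sign, which the naming by a call on the same arrays largely fixed.

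Contractile and mitochondrial genes were lower in cachectic muscle. All 13 fast fibre contractile genes had a negative change, with a median of -0.75, and 3 fell over all genes against 10 adjusted over the list alone (camera, adjusted p = 5.42e-08; adjusted p = 0.401 with an estimated correlation). They were the myosin light chain genes Mylpf (-1.97 ± 0.30, SE) and Myl1 (-0.75 ± 0.10), and parvalbumin (Pvalb, -1.26 ± 0.11). The control means of Myl1 (13.49) and Pvalb (13.73), like that of Actc1, lie near the highest value of 14.49, where a fall can be understated. Skeletal muscle markers had a median of -0.65, 2 called over all genes and 7 adjusted over the list alone (adjusted p = 1.72e-06; adjusted p = 0.401 with an estimated correlation). Myoglobin (Mb) fell by 2.70. On cachectic array 2, the richest in milk protein transcripts, these markers lay at a median of -0.98 against the other muscle arrays. Without that array the median change was -0.37. Slow fibre contractile genes had a median of -0.97 with 0 called over all genes and 1 adjusted over the list alone (adjusted p = 0.00391; adjusted p = 0.486 with an estimated correlation). Without cachectic array 2 their median was -0.57 (limma camera, adjusted p = 0.126), and without it and control array 3 it was -0.52 (0.180). Of 40 genes of oxidative phosphorylation, 39 had a negative change, with a median of -0.61. Over all genes 2 fell, Ndufs1 and Ndufb8 of complex I, against 33 adjusted over the list alone (adjusted p = 8.99e-17; adjusted p = 0.401 with an estimated correlation). The list of thermogenic genes had a median of -0.48 with 2 called over all genes and 3 adjusted over the list alone (adjusted p = 0.0201; adjusted p = 0.401 with an estimated correlation). Without control array 1 it was not called (-0.44; limma camera, adjusted p = 0.0841), and its median was -0.31 without a filter and -0.26 with the milk protein covariate. Its called members were Ckmt2 (-3.04), the mitochondrial creatine kinase of striated muscle, and Cox7a1 (-2.33), a cytochrome oxidase subunit of heart and muscle.

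Matrix genes were lower in cachectic muscle too, with 18 of 25 negative, a median of -0.88, 8 called over all genes and 12 adjusted over the list alone (camera, adjusted p = 3.18e-06; adjusted p = 0.401 with an estimated correlation). Col1a1 (-2.55), Col3a1 (-2.46), Col6a3 (-2.34) and Col1a2 (-2.30) fell. All 12 fibroblast markers were negative, with a median of -1.39, 3 called over all genes and 8 adjusted over the list alone (adjusted p = 5.60e-07; adjusted p = 0.401 with an estimated correlation). Adipocyte identity genes had a median of -0.69, with 1 called over all genes, the glycerol channel Aqp7 (-1.66), and 6 adjusted over the list alone (adjusted p = 0.000319; adjusted p = 0.425 with an estimated correlation). The narrower adipocyte marker list had a median of -0.73 (adjusted p = 0.486 with an estimated correlation), and Lep stood at -3.53 in muscle (limma adjusted p = 0.0590). Adipoq, chosen after its values were seen, averaged 11.49 in control and 10.54 in cachectic muscle, against 12.77 in control adipose tissue and 6.17 in control liver. The muscle samples thus held fat cell transcripts. A lower share of fat was not tested and cannot be told apart here from a fall in muscle for genes that fat also expresses. Fatty acid oxidation genes had a median of -0.26 (adjusted p = 0.401 with an estimated correlation) and an adjusted p of 0.0352 (limma camera). They were not called without cachectic array 1 (-0.32; limma camera, adjusted p = 0.0587), cachectic array 2 (-0.27, 0.0616), cachectic array 3 (-0.33, 0.0580) or control array 1 (-0.24, 0.106). Nor were they called without a filter (-0.13; limma camera, adjusted p = 0.0895), with the milk protein covariate (-0.22, 0.0897) or in the fit of all 18 arrays (0.0550). Cell cycle genes had a median of -0.41 (adjusted p = 0.635 with an estimated correlation), and -0.09 without control array 3 (adjusted p = 0.117). Without control arrays 1 and 2 in turn it was -0.63 and -0.62, without a filter -0.67, and without cachectic array 2 and control array 3 together -0.14 (limma camera, adjusted p = 0.180).

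Genes of protein breakdown and stress hormone response were higher in cachectic muscle. Of 19 atrophy genes, 17 were positive, with a median of 0.81. Over all genes 2 rose, the metallothionein Mt1 (1.89 ± 0.30, SE) and the lysosomal protease Ctsl (1.24 ± 0.14), against 7 adjusted over the list alone (camera, adjusted p = 0.000266; adjusted p = 0.486 with an estimated correlation). The atrophy median was 0.42 without cachectic array 1 and 1.28 without cachectic array 2, and the call was kept. Autophagy and lysosome genes had 20 of 22 positive, a median of 0.32, and 1 called either way of adjusting (adjusted p = 0.000163; adjusted p = 0.401 with an estimated correlation). Proteasome subunits had 30 of 32 positive, a median of 0.34, and 0 called either way (adjusted p = 0.00223; adjusted p = 0.723 with an estimated correlation). They were not called without cachectic array 1 (0.19; limma camera, adjusted p = 0.136) or cachectic array 3 (0.16, 0.0719), and their median was 0.65 without cachectic array 2. Glucocorticoid-induced genes had a median of 0.48, 1 called over all genes and 5 adjusted over the list alone (adjusted p = 0.000291; adjusted p = 0.403 with an estimated correlation). Immediate early genes had a median of 0.45 with Junb (1.09 ± 0.17) called and 6 adjusted over the list alone (adjusted p = 0.00207; adjusted p = 0.401 with an estimated correlation). Acute-phase genes had a median of 1.08, 2 called over all genes and 6 adjusted over the list alone, 5 higher and 1 lower (adjusted p = 0.00262; adjusted p = 0.401 with an estimated correlation). Their median was 0.61 without a filter.

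Leukocyte markers were also higher in cachectic muscle, with calls that ended when single arrays were left out. Macrophage markers had a median of 0.47, 0 called over all genes and 4 adjusted over the list alone (camera, adjusted p = 0.00325; adjusted p = 0.592 with an estimated correlation). They were not called without cachectic array 2 (0.37; limma camera, adjusted p = 0.0667) or cachectic array 3 (0.21, 0.0820), and their median was 0.86 without cachectic array 1. Without cachectic array 2 and control array 3 together it was 0.36 (limma camera, adjusted p = 0.192). Neutrophil markers had a median of 2.29 (adjusted p = 0.0454; adjusted p = 0.401 with an estimated correlation). The call ended without cachectic array 2 (1.77; limma camera, adjusted p = 0.0724), control array 3 (2.28, 0.0754) or both (2.12, 0.0814), and in the fit of all 18 arrays (0.0554). Without a filter the median was 0.90. B and plasma cell markers had a median of 1.53 (adjusted p = 0.0395; adjusted p = 0.536 with an estimated correlation). This call was lost without cachectic array 2 (0.93; limma camera, adjusted p = 0.223), cachectic array 3 (1.55, 0.0952), control array 2 (1.42, 0.0963) or control array 3 (1.61, 0.0792). It also ended without cachectic array 2 and control array 3 together (1.00; limma camera, adjusted p = 0.336), without a filter (0.43, 0.0700) and with the milk protein covariate (1.12, 0.0716). JAK-STAT genes had a median of 0.16 with Il6ra and Junb called (adjusted p = 0.0389; adjusted p = 0.401 with an estimated correlation). The call ended without cachectic array 2 (-0.0087; limma camera, adjusted p = 0.126), cachectic array 3 (0.20, 0.0600) or cachectic array 2 and control array 3 together (0.18, 0.123), and with the milk protein covariate (0.06, 0.106). The median was 0.31 without cachectic array 1 and 0.51 without control array 3. The unfolded protein and integrated stress response had a median of 0.30 (adjusted p = 0.0287; adjusted p = 0.401 with an estimated correlation), and was not called without cachectic array 2 (0.19; limma camera, adjusted p = 0.0912) or in the fit of all 18 arrays (0.0531).

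In all 22 of 35 lists passed in muscle, 11 higher and 11 lower. None, 0 of 22, passed with an estimated correlation or with fry. Regroupings that mixed the groups gave up to 19 lists.

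In liver 405 genes rose and 145 fell of 11920 tested (limma), 310 and 67 of them by at least 1 log2 unit. Oestrogen sulfotransferase (Sult1e1, probeset 10531111) rose by 6.69 log2 units (SE 0.36), from 4.44 ± 0.45 (SD, n = 3) to 11.13 ± 0.67 (SD, n = 3; limma adjusted p = 0.00152). The macrophage chitinase-like gene Chil3 rose from 4.38 ± 0.07 to 9.91 ± 1.28 (limma adjusted p = 0.00630). Thrombospondin 1 (Thbs1) rose from 7.40 ± 0.11 to 11.17 ± 0.97 (limma adjusted p = 0.00819). The chemokines Ccl17 (3.51), Ccl6 (3.45) and Cxcl14 (3.10), the leukocyte receptor gene Lilr4b (3.41) and the protease inhibitor Timp1 (3.27) also rose, with adjusted p from 0.00153 to 0.0343. The organic anion transporter Slco1a1 fell by 5.98, from 11.16 ± 0.71 to 5.18 ± 1.51 (limma adjusted p = 0.010). Carbonic anhydrase 3 (Car3) fell by 5.30, from 13.70 ± 0.06 to 8.40 ± 1.14 (limma adjusted p = 0.00555). Its control level lies near the highest value of 14.49 in the table, where a fall can be understated. The sulfotransferase Sult2a8 (-5.57), the carboxylesterase Ces1f (-4.13), carbonic anhydrase 1 (Car1, -4.05), the liver fatty acid binding protein Fabp1 (-3.37), the methyltransferase Inmt (-3.32) and uridine phosphorylase 2 (Upp2, -3.24) fell, with adjusted p from 0.00211 to 0.0300. The lower mean lay at or under the intensity filter of 6.89 for Sult1e1, Chil3, Lilr4b (6.89), Timp1 (6.23), Slco1a1, Sult2a8 (6.06) and Car1 (5.84), so the sizes of these changes are not exact. As in muscle, these 16 genes were named on condition that the 3 cachectic values lie beyond the 3 control values on 1 side.

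**Figure D2:**
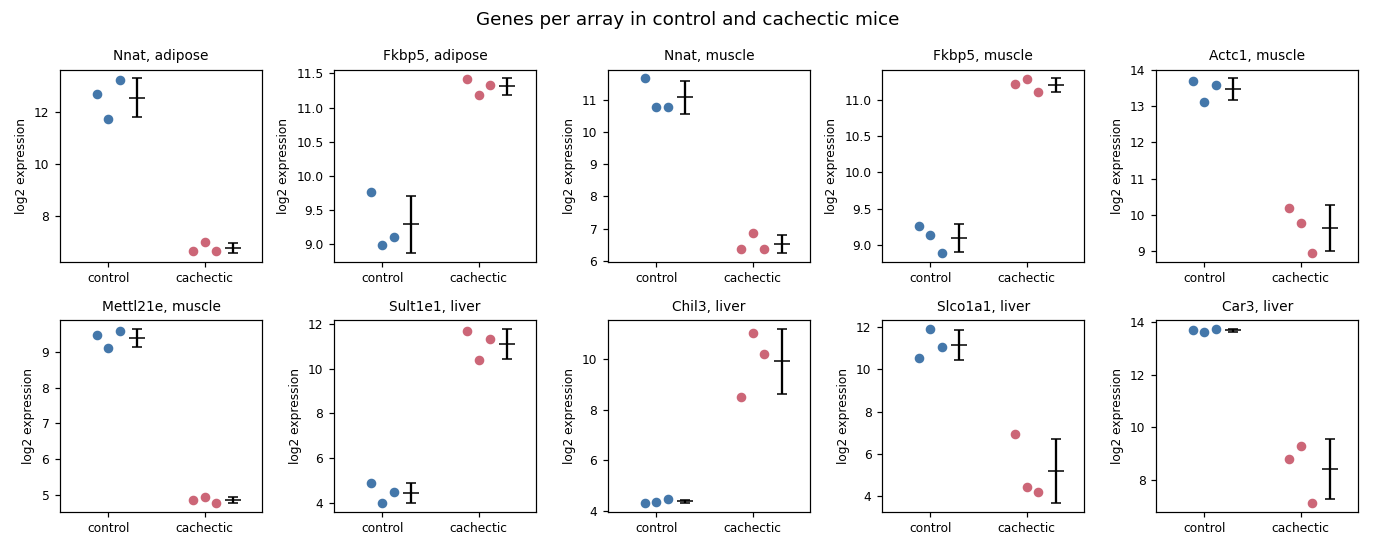
Log2 expression of 10 gene and tissue pairs on each array, with control arrays in blue, cachectic arrays in red, and the mean with its SD over 3 arrays beside each group; the vertical axes do not start at 0. Cachectic and control values do not overlap in any of the 10 panels, including Nnat in adipose tissue (6.78 against 12.55) and Sult1e1 in liver (11.13 against 4.44). The rule for naming genes required this of every pair shown except Fkbp5 in adipose tissue.

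The groups of 3 arrays did not overlap for 3514 genes (29.5%) in liver, where chance gives 10%. The count of 550 genes was 1038 without cachectic array 1, 146, 117 and 148 without control array 1, 2 or 3, and 164 without cachectic array 3, the array richest in mesothelial transcripts. With the mesothelial level as a covariate 40 genes were called, all of them among the 550, and with the milk protein level as a covariate 185 were called, 130 of them among the 550. The mesothelial level was higher on every cachectic liver array than on every control, and the milk protein level was high on cachectic arrays 2 and 3 alone. Each covariate thus overlaps with the group. A call lost with either, here or for the liver lists below, does not separate tissue content from the condition. Of 61 named genes called in liver, 18 passed with each array left out in turn, among them Sult1e1, Chil3, Thbs1, Slco1a1 and Car3. None changed sign, which was again largely fixed by the way they were named.

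Macrophage and matrix genes were higher in cachectic liver. All 16 macrophage markers were positive, with a median of 1.22 and quartiles of 0.96 and 1.56. Over all genes 11 rose, against 15 adjusted over the list alone (camera, adjusted p = 4.21e-13; adjusted p = 0.401 with an estimated correlation). Itgam rose by 2.76 ± 0.22 (SE), the haemoglobin scavenger receptor Cd163 by 1.90 ± 0.13 and Cd68 by 1.53 ± 0.28. The control mean of Itgam (6.39) lay under the filter. Matrix and fibrosis genes had 22 of 24 positive, a median of 0.75, 6 called over all genes and 20 adjusted over the list alone (adjusted p = 5.56e-10; adjusted p = 0.401 with an estimated correlation). Thbs1 (3.77), Timp1 (3.27), Ccn2 (1.70) and lumican (Lum, 1.41) rose. Fibroblast markers had a median of 0.63, 3 called over all genes and 7 adjusted over the list alone, 6 higher and 1 lower (adjusted p = 0.000266; adjusted p = 0.401 with an estimated correlation). Mesothelial markers had a median of 1.34 (adjusted p = 0.00276; adjusted p = 0.497 with an estimated correlation). It was 0.70 without cachectic array 3, and 0.56 with the milk protein covariate, where the call ended (limma camera, adjusted p = 0.164). Ductal epithelial markers had one of 0.60 (adjusted p = 0.00161; adjusted p = 0.401 with an estimated correlation), with Sox9 (1.84) and Krt19 (1.23) called. It was 0.26 without cachectic array 1, and the call ended in the fit of all 18 arrays (limma camera, adjusted p = 0.248). The 12 endothelial markers had a median of 0.25 and were not called (limma camera, adjusted p = 0.171). Without cachectic array 1 their median was 0.63 (limma camera, adjusted p = 0.000135), and with the milk protein covariate it was -0.32 (0.0448). Hepatic stellate cell markers had a median of 0.48 (adjusted p = 0.498 with an estimated correlation). This call was lost without cachectic array 2 (0.47; limma camera, adjusted p = 0.0602), control array 3 (0.51, 0.0555) and with the milk protein covariate (0.33, 0.253). Cholangiocyte markers had one of 1.23 (adjusted p = 0.401 with an estimated correlation), not called without control array 1 (1.26; limma camera, adjusted p = 0.0974) or in the fit of all 18 arrays (0.542).

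Several inflammatory lists were higher in cachectic liver, while interferon-induced genes were lower (median -0.31). Acute-phase genes had 26 of 28 positive, a median of 0.73, 4 called over all genes and 17 adjusted over the list alone (camera, adjusted p = 1.60e-08; adjusted p = 0.401 with an estimated correlation). The endotoxin co-receptor Cd14 (2.60), Apcs (1.52), Lrg1 (0.92) and Serpina3n (0.46) rose. Immediate early genes had a median of 0.80, 6 called over all genes and 10 adjusted over the list alone (adjusted p = 4.63e-06; adjusted p = 0.401 with an estimated correlation), led by Btg2 (2.51) and Klf6 (1.73). Cytokine and chemokine genes had a median of 0.77, 1 called over all genes, Ccl2 (1.99), and 5 adjusted over the list alone (adjusted p = 0.00323; adjusted p = 0.401 with an estimated correlation). Their median was 0.34 without a filter, and 0.15 with the milk protein covariate, where the call ended (limma camera, adjusted p = 0.164). Neutrophil markers had a median of 0.91 (adjusted p = 0.403 with an estimated correlation), and of 0.40 with the milk protein covariate, where the call ended (limma camera, adjusted p = 0.116). B and plasma cell markers had one of 0.69 (adjusted p = 0.475 with an estimated correlation), and of 0.44 without cachectic array 3. Their call ended without a filter (0.0028; limma camera, adjusted p = 0.540), in the fit of all 18 arrays (0.115) and with the milk protein covariate (0.30, 0.189). Glucocorticoid-induced genes had a median of 0.33 with Fkbp5 (1.43 ± 0.28, SE) called and 4 adjusted over the list alone (adjusted p = 0.0189; adjusted p = 0.514 with an estimated correlation). The call ended without cachectic array 1 (0.30; limma camera, adjusted p = 0.104) and control array 3 (0.44, 0.0604), and the median was 0.53 and 0.14 without control arrays 1 and 2.

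JAK-STAT genes in liver had a median of 0.32 and were not called (limma camera, adjusted p = 0.0809). They were called without a filter (0.32; limma camera, adjusted p = 0.0106), with centred arrays (0.25, 0.0443), in the fit of all 18 arrays (0.0265), and without cachectic array 1 (0.37, 0.0310) or control array 1 (0.38, 0.0383). The called members moved apart, the oncostatin M receptor Osmr (2.64) and the feedback inhibitor Socs3 (2.21) higher, Lifr (-2.06) and the IGF carrier subunit Igfals (-1.68) lower.

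Genes of lipid metabolism were lower in cachectic liver. Of 20 genes of fatty acid oxidation and ketogenesis, 19 were negative, with a median of -0.76, 10 called over all genes and 13 adjusted over the list alone (camera, adjusted p = 1.31e-08; adjusted p = 0.401 with an estimated correlation). The peroxisomal thiolase Acaa1b fell by 3.13 (SE 0.25), Acot1 by 1.81, Ehhadh by 1.41 and Cpt2 by 0.89. The cachectic means of Acaa1b (6.46) and Acot1 (6.26) lay under the filter. Of 21 genes of fatty acid and triglyceride synthesis, 19 were negative, with a median of -0.65, 5 called over all genes and 9 adjusted over the list alone (adjusted p = 1.42e-05; adjusted p = 0.403 with an estimated correlation). Their median was -0.40 without cachectic array 3. Acacb fell by 1.83 and Me1 by 1.51. Oxidative phosphorylation had 39 of 40 negative, a median of -0.31, and 0 called either way of adjusting (adjusted p = 1.58e-07; adjusted p = 0.448 with an estimated correlation). With the milk protein covariate the median was -0.19. The 7 male-biased liver genes had a median of -2.81, 1 called over all genes, Slco1a1, and 4 adjusted over the list alone (adjusted p = 0.00483; adjusted p = 0.488 with an estimated correlation), on arrays of which 2 of 3 in each group had high Xist. Without control array 2 their median was -1.86. The 7 female-biased liver genes had a median of -0.78 and were not called (limma camera, adjusted p = 0.525), but were called lower without control array 2, the control with low Xist (-2.12, 0.00205). Hepatocyte markers stood at a median of 0.01 (limma camera, adjusted p = 0.661), and genes of gluconeogenesis and amino acid catabolism at 0.04 (adjusted p = 0.817). The hepatocyte markers averaged 13.55 to 13.70 on the liver arrays, near the highest value of 14.49 in the table, where a change near 0 does not show a stable share of hepatocytes. With the milk protein covariate the latter stood at 0.36 (limma camera, adjusted p = 0.0149).

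Smaller shifts in liver had calls that ended when single arrays were left out. Cytochrome P450 genes had a median of -0.27 with Cyp2c29 (-0.95) called (adjusted p = 0.550 with an estimated correlation). This call was lost without cachectic array 3 (-0.07; limma camera, adjusted p = 0.0628) or control array 3 (-0.30, 0.0596), in the fit of all 18 arrays (0.0909) and with the milk protein covariate (-0.19, 0.163). Without cachectic array 1 the median was -0.42. Bile acid genes had a median of -0.22 with Slco1a1 and the bile salt pump Abcb11 (-0.62) called (adjusted p = 0.509 with an estimated correlation). They were not called without cachectic array 2 (-0.21; limma camera, adjusted p = 0.114), cachectic array 3 (-0.15, 0.0975) or control array 1 (-0.16, 0.122). Nor were they called without a filter (limma camera, adjusted p = 0.108), with centred arrays (0.0866) or with the milk protein covariate (-0.01, 0.316), and the median was -0.40 without cachectic array 1. Cholesterol synthesis had a median of -0.45 (adjusted p = 0.635 with an estimated correlation), and was not called without cachectic array 3 (-0.08; limma camera, adjusted p = 0.217) or with the milk protein covariate (-0.11, 0.0681). Interferon-induced genes had a median of -0.31 (adjusted p = 0.509 with an estimated correlation) and were not called without cachectic array 1 (-0.33; limma camera, adjusted p = 0.0894). Their median was -0.54 and -0.17 without cachectic arrays 2 and 3. Proteasome subunits had a median of -0.17 (adjusted p = 0.699 with an estimated correlation) and were not called without cachectic array 3 (-0.07; limma camera, adjusted p = 0.156). Lipolysis genes had a median of -0.30 with Mgll (-1.71), G0s2 (-1.56) and Plin2 (-0.78) called (adjusted p = 0.401 with an estimated correlation). The call ended without cachectic array 2 (-0.18; limma camera, adjusted p = 0.162) or control array 1 (-0.22, 0.0884). It also ended without a filter (limma camera, adjusted p = 0.153), with centred arrays (0.0775), in the fit of all 18 arrays (0.166), and with Xist (0.0631) or the milk protein level (-0.15, 0.247) as a covariate.

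In all 23 of 39 lists passed in liver, 13 higher and 10 lower. None, 0 of 23, passed with an estimated correlation or with fry. Regroupings that mixed the groups gave up to 23 lists. The median, the mean and the test differed in sign for 3 lists in adipose tissue, 2 in muscle and 6 in liver, none of them called.

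**Figure D3:**
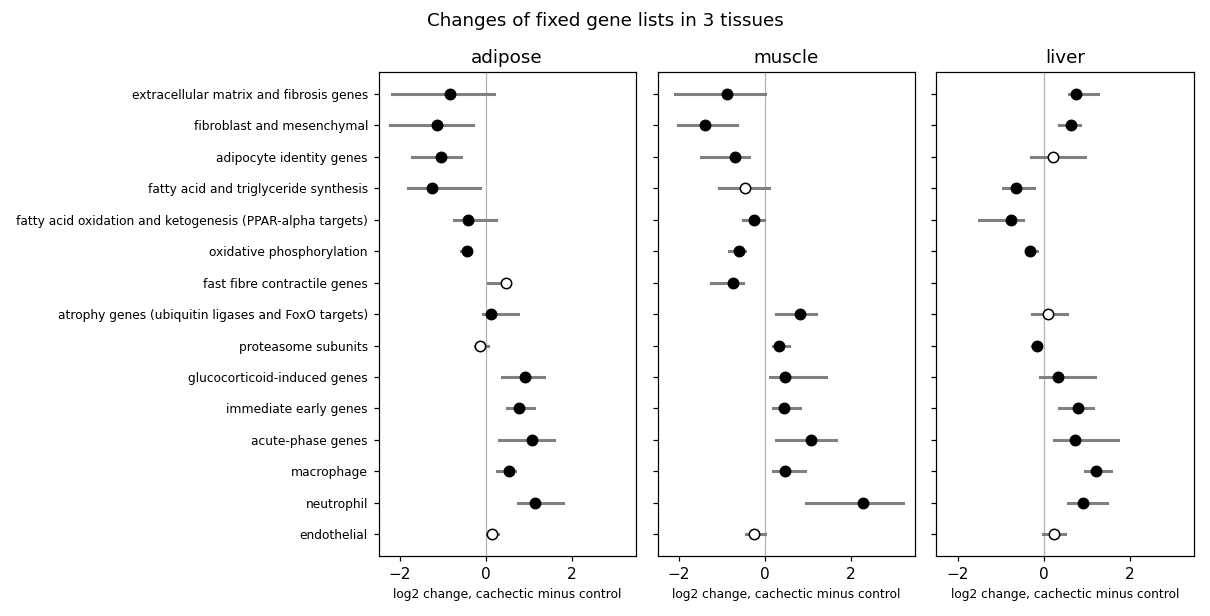
Median log2 change, cachectic minus control, of 15 fixed gene lists in each tissue, with bars from the first to the third quartile of the members; filled points passed camera with the preset correlation, open points did not, and lists with fewer than 5 tested members in a tissue are not drawn. Matrix genes stand at -0.83 in adipose tissue, -0.88 in muscle and 0.75 in liver, and macrophage markers at 0.55, 0.47 and 1.22.

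The changes were then compared between tissues by a test of the difference itself. Matrix genes moved apart between liver and the other tissues, with a median difference of -2.14 for adipose tissue minus liver (camera, adjusted p = 1.83e-20) and -1.96 for muscle minus liver (adjusted p = 1.83e-20), each with an adjusted p = 0.203 with an estimated correlation. Among genes, Nnat changed by -5.77 in adipose tissue, -4.55 in muscle and 0.58 in liver, with differences from liver of -6.35 ± 0.65 (SE; limma, adjusted p = 0.000311) and -5.13 ± 0.65 (adjusted p = 0.00102). The matrix proteoglycan lumican (Lum) changed by -2.57 in adipose tissue, -2.48 in muscle and 1.41 in liver, and the differences from liver were -3.99 and -3.89 (limma adjusted p = 0.0392 and 0.0337). Car3 differed the other way, with -5.30 in liver against -1.12 in adipose tissue and -0.76 in muscle (limma adjusted p = 0.00238 and 0.00102). The secreted protein Ccdc80 (-2.70 against 1.66) and neuregulin 4 (Nrg4, -2.29 against 1.87) differed between adipose tissue and liver, and the Wnt antagonist Frzb (-2.48 against 1.71) between muscle and liver. Means under the filter in 1 group apply here to Nnat in each tissue and to Frzb in muscle (5.92) and liver (6.67). Actc1 changed by -3.82 in muscle, -0.17 in adipose tissue and -0.02 in liver. Mb, Myoz3, Slc16a3 and Jph2, the last a protein of the muscle triad, were also lower in muscle relative to adipose tissue, by differences of 2.97, 2.77, 2.58 and 2.13. With arrays in the same place of the sample order as 1 block, none of the named adipose and muscle differences was called. Those of Nrg4 and Lum between adipose tissue and liver were not called either. That block joined some control arrays with unlike Xist levels.

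The change differed between adipose tissue and muscle for 10 of 11387 genes, between adipose tissue and liver for 126 of 11029, and between muscle and liver for 202 of 10967 (limma; 832, 1252 and 1733 genes at an unadjusted p under 0.05). Without the cachectic and the control array with the most milk protein transcripts in adipose tissue and in muscle the counts were 49, 130 and 661. The count of 10 was 4 without adipose control array 1, 5 without adipose control array 3, 5 without adipose cachectic array 3, 5 without muscle control array 2, 102 without muscle cachectic array 2 and 4 without muscle cachectic array 3. The count of 126 was 69, 70 and 212 without adipose cachectic array 1, control array 3 and cachectic array 3, and 58, 51, 64 and 54 without liver control arrays 1, 2 and 3 and liver cachectic array 3. In the 12 arrays of muscle and liver alone 371 genes were called in place of 202, and 447 with arrays in the same place of the sample order as 1 block. The block gave 0 genes between adipose tissue and muscle and 49 between adipose tissue and liver. In those pairs it joined some control arrays with unlike Xist levels. The count of 202 was 106, 81, 113 and 467 without muscle control arrays 1, 2 and 3 and muscle cachectic array 2, and 119, 103, 122 and 87 without liver control arrays 1, 2 and 3 and liver cachectic array 3.

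Genes called in 2 tissues were few, and those named here were chosen after their values were seen. Muscle and liver shared 7 genes that rose, where independent lists would share 2.03 (Fisher's exact test, two-sided p = 0.00393), namely Fkbp5, the toll-like receptor Tlr4, the riboflavin transporter Slc52a3, Ctsl, galectin 3 (Lgals3), Ccl17 and Lyz1. The lower mean lay under the filter for Tlr4 in liver (6.31) and Ccl17 in muscle (6.86). They shared 9 genes that fell, where independent lists would share 1.41 (Fisher's exact test, p = 1.11e-05), among them Nrep, the mitochondrial glycerol phosphate dehydrogenase Gpd2 and the fatty acid oxidation enzyme Decr1. Fisher's exact test takes genes as independent, which they are not, and arrays of muscle and liver deviate together. Its p-values therefore do not separate a shared response from shared differences between samples. Frzb and Tppp3 fell in muscle and rose in liver. Nnat was the 1 gene called in both adipose tissue and muscle. Fkbp5 had changes of 2.01, 2.09 and 1.43 in adipose tissue, muscle and liver, of which the adipose change did not pass (limma adjusted p = 0.0778). Across genes, which are not independent replicates, the log2 changes correlated with r = 0.638 (rho = 0.548) between adipose tissue and muscle, r = 0.231 (rho = 0.183) between adipose tissue and liver and r = 0.190 (rho = 0.154) between muscle and liver. Milk protein transcripts were high on arrays of both adipose tissue and muscle, and also on cachectic liver arrays 2 and 3. Fat cell transcripts were present in the muscle samples, and their part in the Nnat call and in the correlation with adipose tissue was not tested. Arrays of different tissues can come from the same animal.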

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

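Some of the tests below were chosen after the result was seen. These were the tests of milk protein transcripts, of dilution in adipose tissue and of a lower hepatocyte share in liver. The fits with the milk protein or the mesothelial level as a covariate were also chosen after the result was seen.

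Changes that differed between tissues in a test of the difference itself were looked at again. For genes these were 10 between adipose tissue and muscle, 126 between adipose tissue and liver and 202 between muscle and liver. Of 100 drawn splits of the arrays within the tissues, the real one included, 12 gave as many genes as the 10, so chance was not excluded there, and the highest other split gave 1280. That split kept the adipose groups and exchanged the cachectic and control arrays of muscle, so it added the changes of the 2 tissues (r = 0.638 across genes), and the structure of the samples it points to is that of the groups themselves. For the 126 genes 3 of 100 splits gave as many, with 389 as the highest other, and for the 202 genes 2 of 100, with 723 as the highest other, splits that again point to the structure of the groups. The split with 723 kept the muscle groups and exchanged those of liver, and the split with 389 exchanged those of liver and kept 4 of the 6 adipose arrays in their own group. These splits part arrays of different tissues that deviate together and can come from 1 animal, so they do not decide on chance. Splits that keep the arrays of 1 place together number 10, too few for a share under 0.05, and there the real counts of 10, 126 and 202 stood against 1, 0 and 0 as the highest other. Adipose control arrays 2 and 3 differ in Xist from the arrays in the same place of muscle and liver. In the pairs with adipose tissue these splits therefore can also part arrays of 1 animal.

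Lists that differed between tissues were found by the same kind of test, 22 in all with the preset correlation and 0 with an estimated correlation. Of 100 drawn splits 91 gave as many lists, with 53 as the highest other, so chance was not excluded. For adipose tissue minus muscle the differences of medians were -0.56 for proteasome subunits, 0.19 for oxidative phosphorylation, 0.19 for immediate early genes, 0.38 for endothelial markers, 0.92 for skeletal muscle markers and 1.33 for hepatocyte markers. For adipose tissue minus liver they were 0.16 for glucocorticoid-induced genes, -1.59 for adipocyte identity, -2.14 for matrix genes, -0.89 for cytokines and chemokines, 0.35 for the unfolded protein response, -0.84 for macrophage markers, -1.92 for fibroblast markers and 1.42 for hepatocyte markers. For muscle minus liver they were 0.42 for atrophy genes, 0.49 for proteasome subunits, 0.24 for autophagy and lysosome genes, -0.31 for oxidative phosphorylation, -1.96 for matrix genes, -0.68 for macrophage markers, -2.15 for fibroblast markers and -0.77 for hepatic stellate cell markers. The 2 hepatocyte differences involve cachectic adipose array 3, where these markers averaged 11.44. Without that array their median change in adipose tissue was -0.18 (limma camera, adjusted p = 0.880).

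Probesets outside the analysis by gene also changed, 16 of 5280 without a single gene name in muscle and 20 of 5167 in liver, and 0 of 5480 in adipose tissue (limma).

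Within each tissue the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene in adipose tissue against 0 as the highest other, 270 in muscle against 1, and 550 in liver against 0, and in each tissue 1 split, the real one, gave as many. For lists the real split gave 21 in adipose tissue against 19, and 22 in muscle against 19, with 1 split giving as many. In liver it gave 23 against 23, with 2 splits giving as many.

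Milk protein transcripts were high on part of the adipose and muscle arrays. A response to cachexia cannot be told apart from other differences between mice with high Xist, since the level followed Xist: 3 of 6 cachectic adipose and muscle arrays lay above every control of their tissue, as did 5 of the 6 cachectic arrays with high Xist over the 3 tissues. An adipose array labelled as muscle would carry skeletal muscle markers at adipose level, but on the muscle array richest in milk proteins they lay a median of 3.62 above the best matching adipose array (quartiles 3.33 and 3.87). Mammary gland RNA in the sample remains a candidate explanation, since the epithelial markers of a list fixed earlier exceeded the other muscle arrays by a median of 1.79 on that array, 9 of 16 by over 1 log2 unit, and Wap (14.34), Csn2 (13.79), Krt8 (12.20) and Krt18 (11.59) were abundant. That array correlated with cachectic adipose array 2 at r = 0.983, above the best match of either array within its own tissue (0.956 in muscle and 0.959 in adipose tissue). The other muscle arrays reached at most 0.959 with an adipose array. The added keratins, of which 2 are on both lists, gave an excess of 2.57.

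Matrix genes were lower in cachectic adipose tissue, at a median of -0.83. Milk-rich arrays as the whole cause are argued against by the fit with the milk protein level as a covariate, where the median was -0.85 and 15 of the 16 falling genes kept more than 50% of their fall. Dilution by RNA of another tissue cannot be told apart from a fall in the matrix genes, because endothelial markers exceeded matrix genes by 0.98 but the quartiles of matrix genes (-2.19 and 0.19) overlap those of endothelial markers (0.02 and 0.29). A change in fibroblasts with cachexia stays open and was not tested.

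Macrophage markers and matrix genes were higher in cachectic liver. A lower share of hepatocytes would raise every other cell type alike, but macrophage markers exceeded endothelial markers by 0.97, with quartiles of 0.96 and 1.56 against -0.01 and 0.50. The endothelial median was 0.63 without cachectic array 1 and -0.32 with the milk protein covariate. Mesothelial, cholangiocyte, neutrophil, B and plasma cell, fibroblast, ductal and stellate cell markers were also higher, at medians of 0.48 to 1.34. A lower hepatocyte share as part of the cause is therefore not excluded. Mesothelial tissue on cachectic array 3 alone is argued against as the whole cause. Without that array the macrophage median was 1.12, 16 of 16 markers were higher, and the matrix median went from 0.75 to 0.61. That fit does not remove mesothelial transcripts from the other arrays, since the mesothelial median was still 0.70. With the mesothelial level as a covariate 40 genes were called in liver, against 550 without it. That level was higher on every cachectic liver array (7.03, 7.78 and 9.43) than on every control (at most 7.0). The covariate thus overlaps with the group, and the lower count cannot separate the 2. Mesothelial tissue on more than 1 cachectic array is not excluded as a cause. A response of the liver to the tumour was not tested and cannot be told apart here from a different tissue content of the cachectic samples.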

How the results depend on the processing

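The fits with the milk protein, hepatocyte or mesothelial level as a covariate, those without the cachectic and the control array highest in milk protein level in adipose tissue (cachectic 2, control 2) and muscle (cachectic 2, control 3), and the list tests with Xist as a covariate were chosen after seeing the data. In adipose tissue that fit keeps cachectic array 3, also rich in milk protein transcripts. Where no cause is given, the cause was not tested.

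With each array left out in turn the counts ranged from 0 to 10 genes in adipose tissue, 3 to 1895 in muscle and 117 to 1038 in liver. Fewer arrays also mean fewer degrees of freedom. Without muscle cachectic array 2 there were 1895 genes, and without liver cachectic array 1 there were 1038. The counts of genes whose change differs ranged from 4 to 102 between adipose tissue and muscle, 51 to 212 between adipose tissue and liver, and 81 to 467 between muscle and liver. The counts of lists ranged from 17 to 24, 18 to 24 and 20 to 25 in adipose tissue, muscle and liver.

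The adipose count of 1 gene was 2 without a filter, 3 with the 60th percentile filter, 254 with all 18 arrays in 1 fit, 202 with array weights and 0 with the hepatocyte level as a covariate (limma; 965 genes at an unadjusted p under 0.05 without it). The muscle count of 270 was 960 with all 18 arrays in 1 fit, 5244 with array weights, 158 with Xist as a covariate, 730 with the milk protein level as a covariate and 838 without these milk-rich arrays. The liver count of 550 was 324 with the 60th percentile filter, 1203 with array weights, 185 with the milk protein level and 40 with the mesothelial level as a covariate. In liver the milk protein and mesothelial levels overlap with the group, so the counts of 185 and 40 do not separate tissue content from the condition. Array weights stopped before convergence in some fits.

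Between adipose tissue and muscle the count of 10 was 68 without a filter, 1 with the 60th percentile filter, 498 with array weights and 49 without these milk-rich arrays. Between adipose tissue and liver the count of 126 was 62 with the 60th percentile filter and 229 with array weights. Between muscle and liver the count of 202 was 317 without a filter, 94 with the 60th percentile filter, 2877 with array weights and 661 without these milk-rich arrays.

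The lists called, 21, 22 and 23, were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with the rotation test fry (limma). Genes called the same way in adipose tissue and muscle were 1, then 0 at an adjusted p under 0.01 and 138 with all 18 arrays in 1 fit. In adipose tissue and liver they were 0, then 1 without a filter and 35 in the fit of all arrays. In muscle and liver they were 16, then 0 at an adjusted p under 0.01 and 54 in the fit of all arrays.

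None of the 97 named genes that were called changed direction under the alternatives run. They were named for a call on the same arrays, and those named for the largest changes also for groups that do not overlap. A kept direction was therefore largely fixed by that choice. Of the 134 named genes that were not called, 8 had changes of both signs, among them Cdkn2a in muscle and Xist in each tissue. With 1 array left out, 318 of the 582 fits of a called named gene lost the call, and 30 of all 1386 fits gained one. Centring the arrays lost 6 of 97 calls and gained 3, and the mesothelial covariate lost 49 of 61. Of 396 tests of a called list with 1 array left out 48 lost the call, and 30 of all 654 tests gained one in the same direction. Another 2 gained one with the direction reversed. Only tests of lists not called in the main fit could gain a call. Of 180 fits of a named difference between tissues, 36 lost theirs.

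Among lists called in the main or the alternative fit, the direction of the list test changed in 5 cases, 2 of them with a median on the same side of 0. The list cell cycle and proliferation in adipose had a median of -0.013 without these milk-rich arrays (limma camera, adjusted p = 0.462). The list ductal and tumour epithelial in adipose had -0.97 without control array 3 and 0.89 without cachectic array 1, the lowest and highest of the left-out arrays. The list hepatocyte in muscle had -0.70 without cachectic array 1 and 0.70 without cachectic array 2, again the lowest and highest. With the milk protein covariate, gluconeogenesis and amino acid catabolism in liver had 0.36 and endothelial in liver -0.32.

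The labels number all arrays in 1 series and pair no samples, but the conditions follow in the same order in each tissue. A replicate block for arrays in the same place of 2 tissues was chosen after seeing the data. Between muscle and liver the deviations from the group means correlated in each of the 6 places (r from 0.125 to 0.305), each array matched its own place best, and high or low Xist agreed in all 6. With the block the count of 202 was 447, and 371 in the same 12 arrays with no replicate block, and none of the 5 named differences lost its call. Between adipose tissue and muscle 4 of 6 arrays matched their own place (r from -0.524 to 0.735), and Xist differed on control arrays 2 and 3. The count of 10 was 0 with the block and 3 without it in these 12 arrays. Arrays with high and low Xist cannot come from 1 animal, so the blocks of control arrays 2 and 3 joined different animals. These arrays matched in exchange, adipose control array 2 with muscle control array 3 and adipose control array 3 with muscle control array 2. Their Xist levels go with that exchange (12.37 and 12.19, 5.69 and 6.04). A fit with these blocks exchanged was not run, and the main test takes arrays of different tissues as independent. Between adipose tissue and liver 3 of 6 matched (r from -0.0730 to 0.284), and Xist again differed on control arrays 2 and 3. The count of 126 was 49 with the block, Nrg4 and Lum not among them, and 68 without it. The counts of 0 and 49 therefore do not show the effect of pairing by animal. The lists called were 6, 8 and 9 with the block, against 6, 8 and 8, and the list gained was skeletal muscle markers, muscle minus liver (limma camera, adjusted p = 0.0143).

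Signal over background limits genes near the intensity filter of 6.89 to 6.99 log2, and the counts without a filter and with a stricter filter show the effect.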

Other observations

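The genes in this part were chosen after their values were seen. The ubiquitin ligase genes Trim63 and Fbxo32, which mark atrophy, did not pass in muscle. No other ubiquitin ligase gene of the atrophy list was called higher there, since the 2 members that rose were Mt1 and Ctsl. Trim63 lay at 13.29, 10.50 and 13.10 in cachectic and 11.12, 10.86 and 10.36 in control muscle, a change of 1.52 ± 0.74 (SE; limma adjusted p = 0.307). Fbxo32 lay at 13.15, 11.27 and 13.03 in cachectic and 11.71, 11.78 and 11.27 in control muscle (0.90 ± 0.51; limma adjusted p = 0.374). The low value in both genes belongs to cachectic array 2, the array richest in milk protein transcripts. The myogenic factor Myog had the same arrangement, with 9.72, 6.92 and 9.33 in cachectic muscle.

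In liver 2 of 4 platelet genes passed. Pf4 rose by 1.38 ± 0.25 (SE; limma adjusted p = 0.0323) and Ppbp by 1.24 ± 0.25 (limma adjusted p = 0.0405), while Itga2b stood at 0.93 ± 0.20 (limma adjusted p = 0.0515) and Gp9 at 0.44 ± 0.16 (limma adjusted p = 0.167). Among the male-biased genes, Cyp7b1 stood at -2.81 (limma adjusted p = 0.0563) and Elovl3 at -3.15 (limma adjusted p = 0.146).

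Single arrays also carried transcripts of further tissues. On cachectic adipose array 1 the pancreatic gene Reg1 lay at 8.77 and Zg16 at 9.83. On cachectic liver arrays 2 and 3 Wap lay at 12.30 and 11.36 and Csn2 at 11.53 and 10.37, and Msln lay at 10.90 on cachectic liver array 3. The groups are named by tissue and condition, and no label describes the dissection.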
